A study of Mus musculus with 20 samples.

How the data were processed

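Expression was measured on 20 Affymetrix MOE430B arrays of mouse oocytes and of embryos at 4 later stages, 4 arrays per stage. Per the labels, total RNA was taken through 2 rounds of amplification by in vitro transcription before hybridization. The values deposited by the authors are linear intensities, one per probe set, with 22575 probe sets including 64 controls. The scanner software, the summarization of probes and the target of the scaling are not given in the sources used here. From the values, the mean intensity left after trimming 2% at each end is the same on all deposited arrays to within their rounding, whereas their quantiles differ, so the authors had scaled each array to a common mean and had not quantile normalized. Median intensities per array averaged 74.1 ± 5.13 (SD, n = 4) in oocytes, 73.2 ± 4.46 at the 1-cell stage, 85.8 ± 3.22 at the 2-cell stage, 92.2 ± 1.40 at the 8-cell stage and 87.4 ± 3.28 in blastocysts. The table holds no detection calls, and the number of arrays limits the precision.

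Stages and replicate numbers were taken from the sample titles. No 2 arrays held the same values: at least 99.7% of probe sets differed between any pair. Probe sets were named through the platform's gene annotation, with symbols updated through Entrez identifiers against the mouse gene table of assembly GRCm38.p6, which was used for names only; 14486 of 14661 probe sets with 1 symbol were found there. Of all 22511 probe sets other than controls, 245 carry several symbols and 7605 none, and these were tested but never named. No coordinates are given because no genome build is named for the array.

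Intensities were used as deposited and transformed to log2(value + 20), where 20 is the 20th percentile of the table. Probe sets at or above the table's median of 82.6 on at least 4 arrays were tested, 15234 in all, standing for 7490 named genes. Stage means were fitted in limma 3.58.1 (R 4.3.3) over all 20 arrays, with 15 residual degrees of freedom, and moderated with an intensity trend (eBayes). The comparisons were 1-cell against oocyte, 2-cell against 1-cell, 8-cell against 2-cell, blastocyst against 8-cell, and blastocyst against oocyte. Benjamini-Hochberg adjustment was applied within each, and an adjusted p under 0.05 was called. A moderated F test over the 4 consecutive comparisons gave the probe sets changed among the stages. A 2-cell peak was tested with the larger of the one-sided p-values of its rise and its fall, adjusted in the same way, and its mirror image likewise.

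There were 20 gene lists: oocyte and maternal-effect genes, cleavage-stage zygotic activation genes, ribosome biogenesis, mitochondrial and cytosolic ribosomal proteins, oxidative phosphorylation, proteasome, splicing, mRNA deadenylation and decay, meiosis and spindle, chromatin modifiers and DNA methylation, trophectoderm and epithelium, inner cell mass and pluripotency, primitive endoderm, cholesterol biosynthesis, glycolysis and glucose transport, nuclear transport, and as markers of other cells cumulus and granulosa, sperm and spermatid, and blood and reproductive tract. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation of 0.01. The probe set with the highest mean stood for each gene, and adjustment was over 18 lists and 4 comparisons. That probe set could be of the x_at type, as for Oog3, Prpf19, Epcam, Ctsh, Amhr2 and Dnmt1. Of the listed symbols, older names included, only part was measured: 22 of 132 for oxidative phosphorylation, 11 of 54 for the proteasome and 12 of 83 for zygotic activation. It was 30 of 151 for trophectoderm and epithelium and 9 of 56 for cumulus and granulosa. Calls, and their absence, hold for the measured genes only. Camera compares the genes of a list with all other genes. Fry, an alternative, asks only whether a list's genes change on average, without comparison with other genes. Some genes stand in more than 1 list, 9 of the 48 measured maternal genes among them. A gene is counted as risen or fallen from the adjustment over all probe sets, and again from an adjustment over the list alone.

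Genes were named by a rule: in each consecutive comparison the 8 largest rises and 8 largest falls among called probe sets with 1 symbol, not of the x_at type and not a clone name, whose 4 arrays of one stage all lay above the 4 of the other; up to 4 called members with the smallest p from each list that passed or that the comparison is about, or, where none passed, the 2 most highly expressed; the 10 sharpest 2-cell peaks; and the Dnmt and Tet families with Nanog, Pou5f1, Cdx2 and the Zscan4 family where measured, of which only Dnmt1, Tet1, Tet2 and Tet3 were among the tested probe sets. Of 153 pairs of a named gene and a comparison, 63 had another tested probe set of the gene; in 41 of them it was called the same way and in none the opposite way. Single arrays far from the other 3 of their stage were sought with Dixon's ratio at its critical value of 0.829.

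Design, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives were pseudocounts of 5 and 80, no filter and a filter at the 75th percentile (188.8), quantile normalization, a common 75th percentile, a minimum change of 2-fold, each array left out in turn, the replicate number as a block, no intensity trend, no x_at or s_at probe sets, only the 8 arrays compared, and for lists an estimated correlation, all probe sets of each gene and fry. Array weights and the tests for probe sets lowest or highest at the 1-cell stage were added after seeing the data. The code was tested on simulated data with the spread of the real arrays: with 200 of 15234 probe sets changed between oocyte and 1-cell, it recovered 4.63% of 1.5-fold, 28.5% of 2-fold and 89.2% of 4-fold changes, 5.48% of its calls were false, and 94.2% of 4-fold peaks at the 2-cell stage were found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.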

Results

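Gene expression was measured in mouse oocytes and in embryos at the 1-cell, 2-cell, 8-cell and blastocyst stages on 20 Affymetrix MOE430B arrays, 4 per stage. The period runs from the oocyte, which holds stored maternal transcripts, through activation of the embryonic genome to the blastocyst. The blastocyst has an outer trophectoderm and an inner cell mass. Total RNA had been taken through 2 rounds of amplification by in vitro transcription. After removal of control and dim probe sets 15234 of 22511 probe sets were tested, of which 10478 carry 1 gene symbol, 178 carry several and 4578 carry none. Nothing in the labels says that the 4 replicates of a stage came from separate pools of embryos, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. All log2 changes are on the log2(value + 20) scale, which understates the change of low genes, and the lowest intensities cannot be separated from background because the value table carries no detection calls.

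The median correlation within each stage was higher than that of the same stage with any other, although single pairs overlapped, with oocyte and 1-cell arrays correlating at up to 0.887 and 1-cell arrays with one another at 0.844 or more. The median correlation across probe sets, which are not independent replicates, was 0.90 among oocyte arrays, 0.884 among 1-cell arrays, 0.872 among 2-cell arrays, 0.839 among 8-cell arrays and 0.845 among blastocyst arrays. Between consecutive stages it was 0.853 from oocyte to 1-cell, 0.706 from 1-cell to 2-cell, 0.598 from 2-cell to 8-cell and 0.723 from 8-cell to blastocyst. Expression of 8078 probe sets, or 53% of those tested, changed among the 5 stages by limma's moderated F test. The 2-cell arrays were the most spread along the first principal component, with scores from -29.7 to -0.95, an SD of 12.3, against SDs from 1.00 to 4.76 in the other stages.

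**Figure D1:**
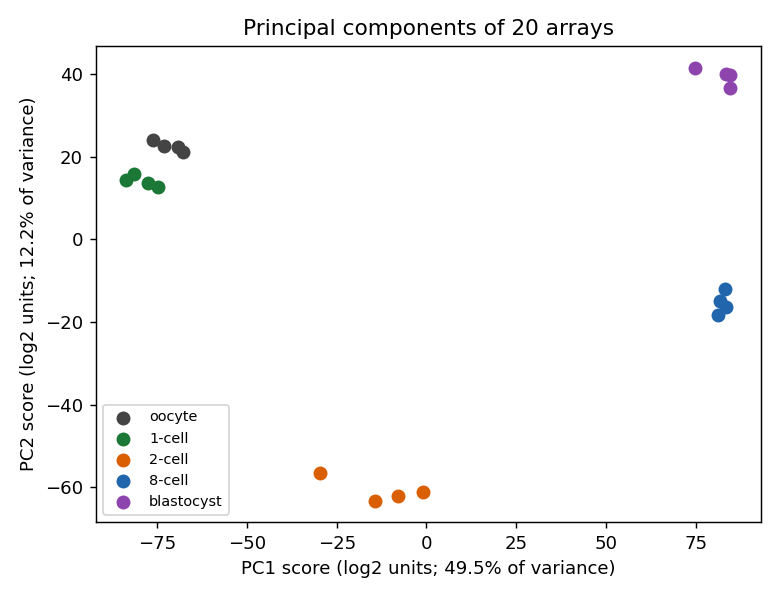
Scores of the 20 arrays on the first (x axis, 49.5% of variance) and second (y axis, 12.2% of variance) principal components of the log2 intensities, in log2 units, coloured by stage; each point is an array. The 2-cell arrays lie between the oocyte and 1-cell arrays on the left and the 8-cell and blastocyst arrays on the right, at scores from -29.7 to -0.95 on the first component.

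Some control probe sets differed by stage. The middle probe set of 18S ribosomal RNA read 37010 ± 4510 (SD, n = 4) on the 1-cell arrays. It read 650.2 ± 197 in oocytes, 2004 ± 308 at the 2-cell stage, 3282 ± 854 at the 8-cell stage and 2592 ± 473 in blastocysts. All 4 values of the 1-cell stage lay above all 4 of the oocytes (2-sided exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give). After Benjamini-Hochberg adjustment over 48 tests of control probe sets it was 0.0528. The 18 bacterial control probe sets were on average 1.65 log2 units brighter on the 8-cell arrays than on the oocyte arrays, and 0.56 to 0.71 units brighter at the other stages, after the authors' scaling of every array to 1 mean. How and at which step these bacterial RNAs were added is not given in the sources used here, so their brightness is a value only.

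**Figure D2:**
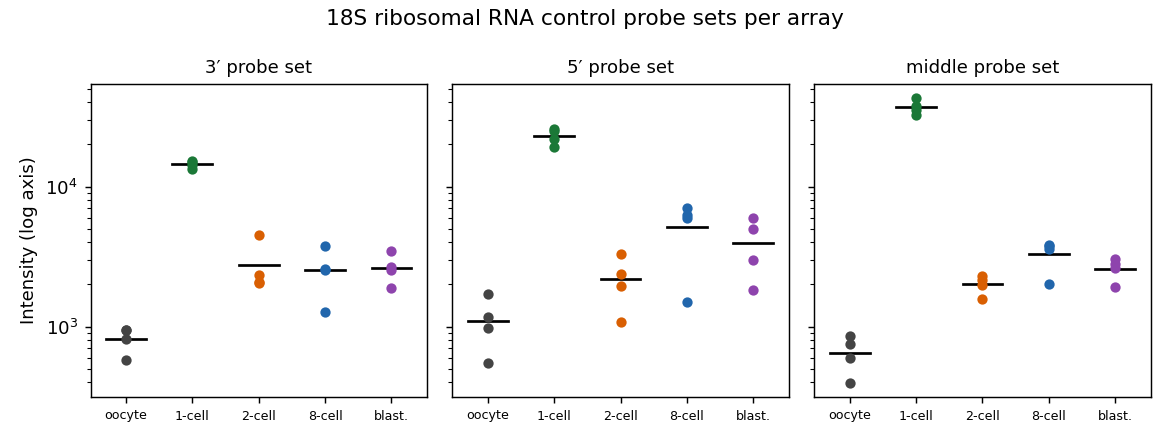
Intensity (y axis, log scale) of the 3 control probe sets of 18S ribosomal RNA on each array by stage (x axis); points are arrays and bars are stage means, n = 4. In each panel the 4 arrays of the 1-cell stage lie above the other 16, with a mean of 37010 for the middle probe set.

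The comparison of 1-cell embryos with oocytes spans fertilization. The sample titles read only oocyte, so whether the step also spans maturation of the oocyte is not known here. The largest falls included Psmc3ip, a partner of the meiotic recombinases, from 1281 ± 353 (SD, n = 4) to 53.8 ± 28.5, and Dscc1, a subunit of an alternative clamp loader, from 773.9 ± 143 to 40.2 ± 30.3. Their log2 changes were -4.2 (adjusted p = 1.87e-10) and -3.88 (adjusted p = 2.5e-09). Fbxw13, an oocyte F-box gene, fell from 5272 ± 1010 to 457.8 ± 40.9. Ppil3, a peptidylprolyl isomerase, fell from 3474 ± 364 to 325.9 ± 107. Rnaseh2a, the catalytic subunit of ribonuclease H2, fell from 396.7 ± 105 to 23.3 ± 16.8. Abhd17a (387.5 ± 72.2 to 17.9 ± 6.41), Dcdc2c (329.1 ± 65.7 to 12.6 ± 6.59) and Cage1 (533.6 ± 226 to 36.2 ± 23.1) fell as well. Rises were smaller. Abhd17b went from 17.6 ± 4.95 to 225.2 ± 78.5, a log2 change of 2.66 (adjusted p = 1.32e-06). Mcu, the mitochondrial calcium uniporter, rose from 30.2 ± 19.6 to 230.4 ± 57.7 and Tbl1xr1, a corepressor subunit, from 169.1 ± 39.5 to 759.9 ± 205. Atp2c1, a Golgi calcium pump, rose from 138.6 ± 18 to 634.2 ± 243 and Septin14 from 24.3 ± 22.6 to 146 ± 70.5. Cep164, Tnks and Ipcef1 also rose, by 2.60, 2.40 and 2.42 log2 units. In each, however, a single oocyte array stood apart from the other 3, at 342.6 against at most 69.2 for Cep164, at 352.8 against at most 59.8 for Tnks and at 117.5 against at most 12.5 for Ipcef1.

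By camera the oxidative phosphorylation and proteasome lists were shifted down at the 1-cell stage, although most of their genes did not pass and both calls were lost with an estimated correlation. Of 22 measured genes of oxidative phosphorylation, 5 fell, none rose and 17 did not pass (5 and none adjusted over the list alone; adjusted p = 0.00537 by camera, and adjusted p = 0.0803 with an estimated correlation). Ndufc2, a subunit of respiratory complex I, fell from 3492 ± 214 to 595.7 ± 182, and Sdhaf3, an assembly factor of succinate dehydrogenase, from 663.1 ± 53.7 to 158.8 ± 30.1. Ndufaf8, a complex I assembly factor, fell from 1387 ± 241 to 409.9 ± 143. Ndufaf6, another, fell from 602.6 ± 216 to 44.6 ± 24.8, with replicate 3 apart at 924.6 among the oocytes and at 81.6 among the 1-cell arrays. Of 11 proteasome genes, 3 fell, none rose and 8 did not pass (3 and none adjusted over the list alone; adjusted p = 0.0413, and adjusted p = 0.137 with an estimated correlation). Psmb5, a catalytic subunit, fell from 1317 ± 120 to 318.6 ± 65.0, Psma1 from 2937 ± 655 to 1398 ± 85.7 and Psmc5 from 1897 ± 366 to 727.5 ± 244. The median level of the proteasome list, averaged over arrays, went the other way, from 7.505 ± 0.43 to 7.82 ± 0.30 log2 units. The falls of these genes go together with the 18S signal, 5.83 log2 units higher on the 1-cell than on the oocyte arrays for the middle probe set. Over the same step the beta-actin 3'/5' log2 ratio went from 2.36 ± 0.13 to 1.83 ± 0.36 and that of Gapdh from 1.99 ± 0.19 to 2.12 ± 0.26. The oocyte and maternal-effect list did not pass (adjusted p = 0.661). Of its 48 genes 3 rose, 7 fell and 38 did not pass (5 and 10 adjusted over the list alone). The median log2 change was 0.02 and the mean -0.16. Khdc3 and Fbxw21 from that list fell from 2305 ± 358 to 575 ± 180 and from 8867 ± 906 to 2878 ± 696.

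In all, 406 probe sets were higher and 649 lower at the 1-cell stage than in oocytes at an adjusted p under 0.05, and 179 and 485 of these by at least 2-fold. Without 1-cell replicate 2 the higher count came to 257. The proteasome call was lost without oocyte replicate 2 (adjusted p = 0.102), oocyte replicate 4 (adjusted p = 0.0791) or 1-cell replicate 2 (adjusted p = 0.0635), and under 5 other choices: a pseudocount of 80 (adjusted p = 0.0615), no filter (adjusted p = 0.068), the 75th percentile filter (adjusted p = 0.0565), no intensity trend (adjusted p = 0.0556) and array weights (adjusted p = 0.0691). The oxidative phosphorylation call was lost without x_at and s_at probe sets, which can share sequence between genes (adjusted p = 0.133). Without 1-cell replicate 4, mitochondrial ribosomal proteins (adjusted p = 0.0434, from 0.0725) and cholesterol biosynthesis (adjusted p = 0.0477, from 0.0851) were called as well.

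**Figure D3:**
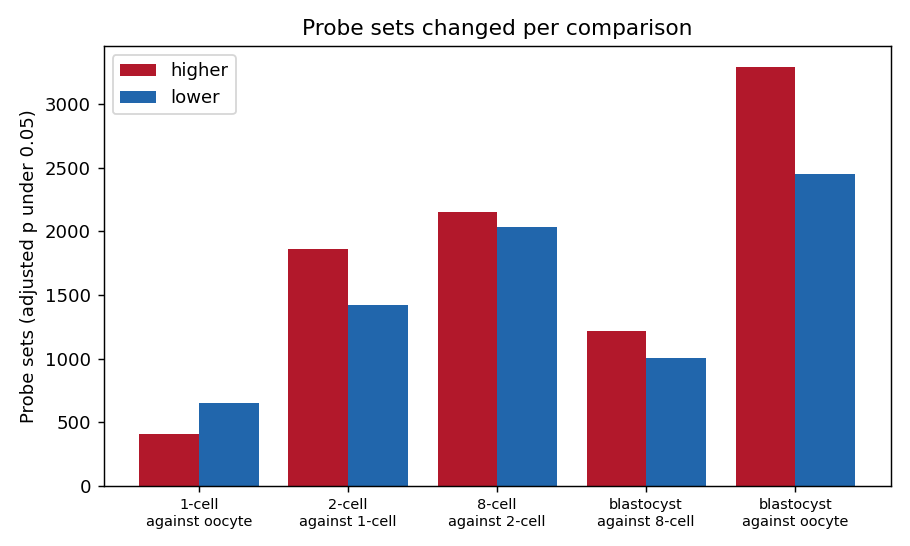
Number of probe sets (y axis, starting at 0) that were higher or lower at an adjusted p under 0.05 in each of 5 comparisons of stages (x axis), out of 15234 tested. The count ran from 406 higher and 649 lower between oocyte and 1-cell to 3292 higher and 2449 lower between oocyte and blastocyst.

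The comparison of 2-cell with 1-cell embryos spans the main activation of the mouse embryonic genome. Obox6, a homeobox gene of a family active in oocytes and early embryos, rose from 40.9 ± 14.3 (SD, n = 4) to 7828 ± 800, a log2 change of 7.04 (adjusted p = 5.34e-19). Ubtfl1, an HMG-box gene of the early embryo, rose from 30.9 ± 28.2 to 4557 ± 588 by 6.66 log2 units (adjusted p = 1.51e-13). Wdr44 rose from 5.68 ± 1.18 to 1783 ± 482 and Zfp367 from 5.75 ± 3.22 to 1715 ± 259. Gigyf2, a repressor of translation, rose from 8.40 ± 3.51 to 1173 ± 242, and Ppm1a, a protein phosphatase, from 40.3 ± 14.4 to 2734 ± 626. Ifi35 rose from 38.3 ± 22.9 to 2590 ± 330 and Pramel18 from 11.1 ± 11.4 to 1314 ± 423. Falling transcripts included Pabpn1l, a poly(A)-binding protein of oocytes, from 1624 ± 380 to 23.2 ± 9.59 (log2 change -5.25, adjusted p = 5.4e-15). The spindle checkpoint kinase Bub1b fell from 17960 ± 4910 to 630.1 ± 234 and the DNA damage checkpoint kinase Chek1 from 1676 ± 152 to 71.5 ± 36.7. Rgs2, a regulator of G-protein signalling, fell from 14680 ± 648 to 747.5 ± 282. Ccdc14 (1599 ± 388 to 53.7 ± 46.1), Acoxl (570.9 ± 103 to 14.9 ± 6.59), Diras2 (731.6 ± 210 to 38.9 ± 31.4) and Zfp873 (499.1 ± 96.8 to 19.5 ± 19.7, with 2-cell replicate 1 apart at 49.0) also fell.

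By camera the oocyte and maternal-effect list was shifted down and the zygotic activation and ribosome biogenesis lists up, although in each some genes went the other way or did not pass. Of 48 oocyte and maternal-effect genes, 31 fell, 4 rose and 13 did not pass (34 and 4 adjusted over the list alone; median log2 change -1.28, adjusted p = 8.09e-11, and adjusted p = 0.0175 with an estimated correlation). Zar1, required for the oocyte-to-embryo transition, fell from 14690 ± 2340 to 1190 ± 293, and Fbxw22 from 23550 ± 1650 to 3451 ± 769, with 2-cell replicate 1 apart at 4596. Obox6, which rose, stands in the same list. Of 12 cleavage-stage activation genes, 6 rose, 1 fell and 5 did not pass (6 and 1 adjusted over the list alone; median 0.71, adjusted p = 0.00153, and adjusted p = 0.0169 with an estimated correlation). Besides Ubtfl1 these included Ddit4l, from 228.5 ± 73.7 to 1528 ± 310, Zfp809, from 64.5 ± 37.4 to 389.2 ± 36.7, and the splicing regulator Rbm25, from 102.1 ± 27.6 to 567.1 ± 122. Of 53 ribosome biogenesis genes, 24 rose, 8 fell and 21 did not pass (25 and 8 adjusted over the list alone; median 0.70, adjusted p = 3.17e-05, and adjusted p = 0.0289 with an estimated correlation). Utp14b rose from 418.6 ± 85.3 to 5671 ± 574, and Tsr1 from 441.5 ± 96.6 to 3892 ± 941. Krr1 rose from 302.9 ± 41.8 to 1896 ± 238 and Wdr3 from 215 ± 36.6 to 2392 ± 531, with 2-cell replicate 3 apart at 3180. Krr1 had read 1580 ± 64.3 in oocytes, so its rise was largely a return to that level. In all, 7 genes of the list, Krr1 and Wdr3 among them, were lowest at the 1-cell stage. The list's median level, averaged over arrays, was 8.00 log2 units in oocytes, 7.91 at the 1-cell and 8.65 at the 2-cell stage. The 18S signal fell by 4.2 log2 units over the same step for the middle probe set.

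In all, 1859 probe sets were higher and 1423 lower at the 2-cell than at the 1-cell stage, of which 1413 and 988 by at least 2-fold.

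A peak at the 2-cell stage, higher than both the 1-cell and the 8-cell stage, was found for 219 probe sets, and 86 were lowest there. The sharpest was Pramel18, of a family expressed in germ cells and embryos, at 11.1 ± 11.4 (SD, n = 4), 1314 ± 423 and 7.28 ± 2.71 through the 1-cell, 2-cell and 8-cell stages. The smaller of its log2 changes, from levels near background, was 5.43 (adjusted p = 4.23e-11 for the peak). Speer4cos read 30.6 ± 19.3, 1152 ± 323 and 46.4 ± 26.4, and Kansl1, of a histone acetyltransferase complex, 32.2 ± 14.4, 1045 ± 179 and 47.5 ± 28.7. Rfpl4b read 54.8 ± 28.5, 1549 ± 368 and 99.1 ± 82.4, and Foxj3, a forkhead factor, 93.1 ± 23.5, 1229 ± 196 and 90.0 ± 30.2. Ikzf5 (792.6 ± 104), Tchp (412.4 ± 88.0), Zfp647 (1328 ± 163) and Exoc3l2 (2144 ± 353) peaked as well. So did the kinase gene Cdk13 at 899.5 ± 197, although its replicate 3 lay apart at 14.9 among the 1-cell and at 6.0 among the 8-cell arrays. Called rises followed by called falls numbered 358, against 248.6 for independent lists of these sizes. The mirror image, called falls followed by called rises, numbered 239, against 201.3. At an unadjusted p under 0.05 rises followed by falls numbered 562, against 79.0 in simulations of unchanged stages sharing the 2-cell arrays. No probe set changes in these simulations, so they speak on noise alone and not on an excess of peaks. With the rise read from 2 of the 2-cell arrays and the fall from the other 2, the overlap was 220 to 266, against 114 to 176 for independent lists.

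**Figure D4:**
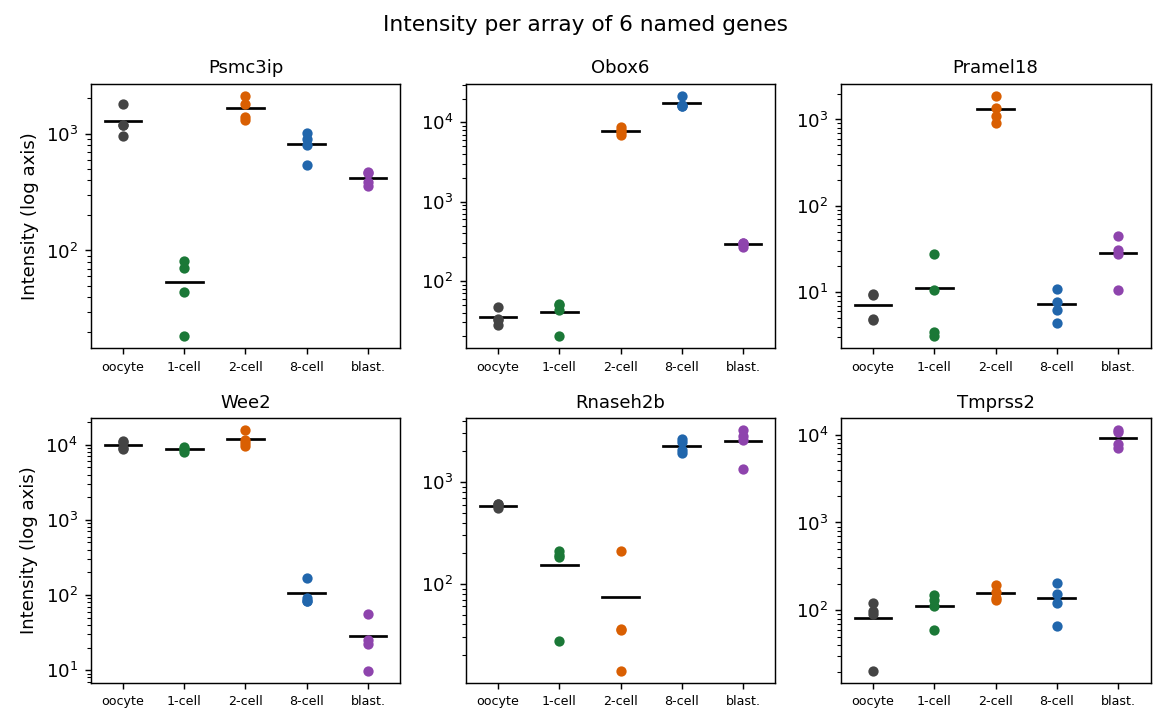
Intensity (y axis, log scale) of 6 named genes on each array by stage (x axis); points are arrays and bars are stage means, n = 4. Psmc3ip is lowest at the 1-cell stage (mean 53.8), Obox6 and Pramel18 rise at the 2-cell stage (means 7828 and 1314), Wee2 falls to 106.2 and Rnaseh2b rises to 2280 at the 8-cell stage, and Tmprss2 reaches 9176 in blastocysts.

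The comparison of 8-cell with 2-cell embryos covers cleavage, and gave the largest number of changes between the consecutive stages measured. No stage between these was measured, so when within this step a change occurred is not known, and steps differ in length. Wee2, the kinase that holds oocytes in meiotic arrest, fell from 11740 ± 2620 (SD, n = 4) to 106.2 ± 41.2, a log2 change of -6.57 (adjusted p = 4.23e-16), with 8-cell replicate 2 apart at 167.8. Trim61 fell from 4107 ± 2180 to 25.6 ± 22.3, Klhl8 from 2541 ± 366 to 26.9 ± 7.67, and Pramel18 returned to 7.28 ± 2.71. Bmp15, an oocyte growth factor, fell from 2246 ± 597 to 45.1 ± 53.6, where 8-cell replicate 4 lay apart at 124.7. Of the Nlrp family of oocyte genes, Nlrp4f fell from 13330 ± 2220 to 138.1 ± 30.5, with 8-cell replicate 3 apart at 92.4, Nlrp4e from 1623 ± 734 to 22.9 ± 15.8 and Nlrp9c from 2726 ± 1460 to 55.9 ± 39.6. Vnn1, a pantetheinase, rose from 26.3 ± 35 to 4879 ± 933 by 6.95 log2 units (adjusted p = 1.45e-13), with 2-cell replicate 1 apart at 78.5. Rragd, a GTPase of amino acid sensing, rose from 152.6 ± 28.6 to 4913 ± 1010 and Tmem64 from 83.2 ± 12 to 3985 ± 757. Epas1, a hypoxia-inducible factor, rose from 77.9 ± 27.3 to 2241 ± 493, and the RNA-binding Syncrip from 73.2 ± 23.4 to 2136 ± 70.9. Ddah1 (9.03 ± 4.24 to 681.2 ± 106), Gk5 (64.6 ± 58.2 to 1625 ± 437) and Rnaseh2b (74.0 ± 91.9 to 2280 ± 324, with 2-cell replicate 1 apart at 211) rose too.

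Of the 48 oocyte and maternal-effect genes, 36 fell, 2 rose and 10 did not pass (37 and 2 adjusted over the list alone; median -2.68, adjusted p = 2.48e-21, and adjusted p = 0.00534 with an estimated correlation). Oog3 fell from 12040 ± 6390 to 76.1 ± 46.7 and Oosp3 changed by -5.13 log2 units. Of 11 proteasome genes, 8 rose, none fell and 3 did not pass (8 and none adjusted over the list alone; median 1.5, adjusted p = 0.000198, and adjusted p = 0.0169 with an estimated correlation). Psma1 rose from 1153 ± 172 to 6274 ± 554, Psmb5 from 2187 ± 503 to 6150 ± 820, Psmc5 from 370.6 ± 92.7 to 2226 ± 607 and Psma3 from 77.8 ± 43.1 to 335.3 ± 43.2. Of 24 mitochondrial ribosomal protein genes, 12 rose, none fell and 12 did not pass (13 and none adjusted over the list alone; median 0.62, adjusted p = 0.00095, and adjusted p = 0.0134 with an estimated correlation). Mrpl27 rose from 507.7 ± 101 to 2235 ± 360, Mrps10 from 83.2 ± 52.7 to 856.6 ± 103 and Mrpl44 from 16.6 ± 1.44 to 277.1 ± 66.4. Of 52 splicing genes, 22 rose, 1 fell and 29 did not pass (25 and 2 adjusted over the list alone; median 0.58, adjusted p = 0.000377, and adjusted p = 0.0134 with an estimated correlation). Snrpb, a core snRNP protein, rose from 1175 ± 351 to 6969 ± 396 and Prpf19 from 3168 ± 704 to 10620 ± 1870. The helicase Ddx46 fell from 660.6 ± 218 to 71.6 ± 3.68, with 8-cell replicate 1 apart at 77.1. Of 53 ribosome biogenesis genes, 22 rose, 4 fell and 27 did not pass (23 and 4 adjusted over the list alone; median 0.54, adjusted p = 0.000999, and adjusted p = 0.102 with an estimated correlation). Wdr3 rose on to 7260 ± 706 and Krr1 to 4335 ± 370, whereas Utp14b fell back to 920.1 ± 282. The bacterial control probe sets were brighter on the 8-cell than on the 2-cell arrays as well, at 12.6 ± 0.34 against 11.5 ± 0.24 log2 units. The 3'/5' log2 ratio of Gapdh, a measure of RNA or amplification length, was 0.98 ± 0.37 against 2.22 ± 0.34.

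In all, 2155 probe sets were higher and 2037 lower at the 8-cell than at the 2-cell stage, of which 1495 and 1578 by at least 2-fold. The trophectoderm and epithelium list, with 13 of 30 genes higher and 3 lower, did not pass by camera (adjusted p = 0.0981). It was called without 2-cell replicate 2 (adjusted p = 0.0484) and by fry (adjusted p = 2.34e-05). Fry also called inner cell mass and pluripotency (adjusted p = 0.00244) and primitive endoderm (adjusted p = 0.0294) at the 8-cell stage. It had called inner cell mass and pluripotency at the 2-cell stage as well (adjusted p = 1.59e-05).

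**Figure D5:**
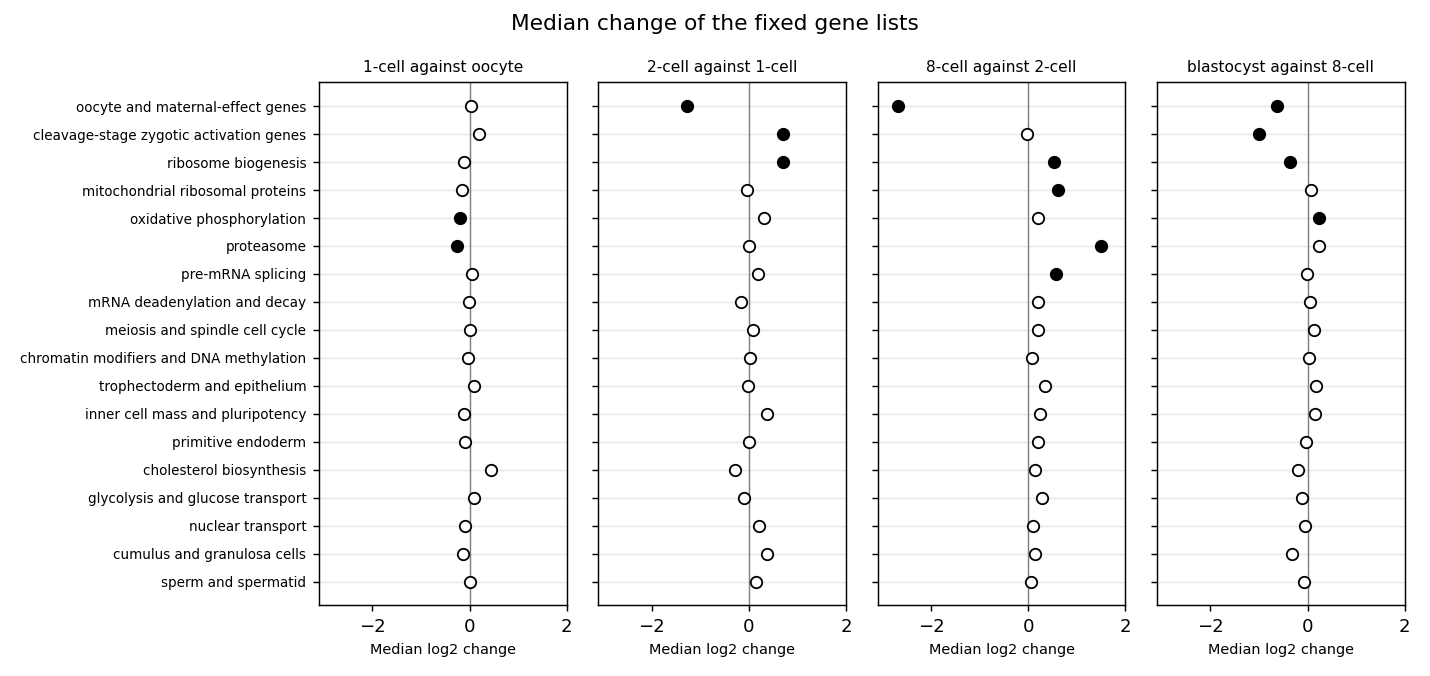
Median log2 change (x axis) of the measured genes of 18 lists (y axis) in the 4 comparisons of consecutive stages (panels); filled circles have a camera adjusted p under 0.05. The oocyte and maternal-effect list had its lowest median, -2.68, between the 2-cell and 8-cell stages, and the proteasome its highest, 1.5.

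The comparison of blastocysts with 8-cell embryos covers the formation of the first cell lineages. Tmprss2, a transmembrane serine protease of epithelia, rose from 136.5 ± 57.0 (SD, n = 4) to 9176 ± 2000, a log2 change of 5.93 (adjusted p = 4.24e-12). Csta1, a cysteine protease inhibitor, rose from 110.9 ± 32.7 to 3065 ± 648 and Vgll3, a cofactor of TEAD factors, from 45 ± 27.5 to 1278 ± 541. Gulp1, an engulfment adaptor, rose from 29.7 ± 31.0 to 841.4 ± 224, and P2rx3, an ATP-gated channel, from 11.2 ± 8.34 to 546.9 ± 102. Gins2, a part of the replicative helicase, rose from 67.3 ± 17.2 to 2026 ± 265. Magi3, a junctional scaffold, rose from 23.8 ± 3.28 to 743.3 ± 154, and Tmem125 from 35.8 ± 20.3 to 957.4 ± 228, with 8-cell replicate 1 apart at 66.0. Obox6 fell from 17580 ± 2810 to 290.5 ± 15 (log2 change -5.81, adjusted p = 4.45e-17), with 8-cell replicate 1 apart at 21768. The Krüppel-like factor Klf17 changed by -4.32 log2 units, to 94.1 ± 38.9, with 8-cell replicate 3 apart at 1977 and blastocyst replicate 1 at 152.4. Larp4 fell from 16170 ± 1850 to 1534 ± 723, and Fbxl20 from 9258 ± 607 to 745.1 ± 132. Ppm1a fell from 2615 ± 575 to 176.3 ± 26.0, Sapcd2 from 611.2 ± 122 to 26.8 ± 8.45 and Rnf122 from 466.8 ± 134 to 22.6 ± 5.29. Tent5c, a poly(A) polymerase, fell from 489.3 ± 41.3 to 24.2 ± 9.93.

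Of 12 cleavage-stage activation genes, 7 fell, 1 rose and 4 did not pass (7 and 1 adjusted over the list alone; median -0.998, adjusted p = 0.00065, and adjusted p = 0.0134 with an estimated correlation). Ubtfl1 fell to 213.2 ± 117 and Ddit4l to 297.6 ± 72.7. Of the 48 maternal genes, 16 fell, 3 rose and 29 did not pass (23 and 5 adjusted over the list alone; median -0.63, adjusted p = 0.000377, and adjusted p = 0.164 with an estimated correlation). Khdc3 and Ooep, both of the subcortical maternal complex, were among those that rose, from 3707 ± 500 to 20820 ± 2270 and from 352.7 ± 62.0 to 2101 ± 513, while Nlrp14 fell from 310.6 ± 74.2 to 39.9 ± 41.6. Of 53 ribosome biogenesis genes, 12 fell, 1 rose and 40 did not pass (15 and 2 adjusted over the list alone; median -0.37, adjusted p = 0.00536, and adjusted p = 0.137 with an estimated correlation). Tbl3 fell from 1619 ± 245 to 665.6 ± 124 and Rrn3 from 886 ± 145 to 432.6 ± 84.5. Of 22 oxidative phosphorylation genes, 6 rose, none fell and 16 did not pass (6 and none adjusted over the list alone; median 0.24, adjusted p = 0.0178, and adjusted p = 0.118 with an estimated correlation). Ndufc2 rose to 4424 ± 593 and Uqcrh, of complex III, to 2343 ± 715.

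The lineage lists did not pass by camera. Fry called trophectoderm and epithelium (adjusted p = 0.000495) and inner cell mass and pluripotency (adjusted p = 1.59e-05) but not primitive endoderm (adjusted p = 0.561). Of 30 trophectoderm and epithelium genes, 7 rose, 2 fell and 21 did not pass (7 and 2 adjusted over the list alone; adjusted p = 0.164). Of 29 inner cell mass and pluripotency genes 8 rose, 3 fell and 18 did not pass (10 and 4 adjusted over the list alone; adjusted p = 0.229). Epcam, an epithelial adhesion molecule, rose from 893.4 ± 57.5 to 2764 ± 571 and Tead1, a transcription factor of the Hippo pathway, from 1156 ± 282 to 2878 ± 717. Ptges, a prostaglandin E synthase, rose from 105.3 ± 25.6 to 728.3 ± 494. L1td1, an RNA-binding protein of pluripotent cells, rose from 409.9 ± 178 to 6305 ± 3570. Of the same list as L1td1, Il6st changed by 1.95 and Rif1 by -0.98 log2 units. Of 19 primitive endoderm genes, 3 rose, 2 fell and 14 did not pass (3 and 2 adjusted over the list alone; adjusted p = 0.96). The list's median log2 change was -0.03 while its mean was 0.21 and the test pointed up. The receptor Pdgfra, an early marker of that lineage, rose from 93.8 ± 53.3 to 315.9 ± 63.5. Flrt3 and Dkk1 of the same list rose by 2.855 and 1.964 log2 units. The protease Ctsh fell from 719.5 ± 236 to 200.5 ± 26.0.

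In all, 1215 probe sets were higher and 1003 lower in blastocysts than at the 8-cell stage, of which 858 and 653 by at least 2-fold. The bacterial control probe sets were dimmer on the blastocyst arrays, at 11.6 ± 0.40 log2 units. The 3'/5' log2 ratio of beta-actin was 1.09 ± 0.27 against 1.92 ± 0.10 at the 8-cell stage, and that of Gapdh went the other way, to 2.37 ± 0.46 from 0.98 ± 0.37. The oxidative phosphorylation call was lost without 8-cell replicate 4 (adjusted p = 0.0558), blastocyst replicate 1 (adjusted p = 0.052), the filter on low values (adjusted p = 0.0773) or x_at and s_at probe sets (adjusted p = 0.123).

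Between the ends of the series, 3292 probe sets were higher and 2449 lower in blastocysts than in oocytes. L1td1 differed by 7.21 log2 units (adjusted p = 1.52e-14), Tmprss2 by 6.60 (adjusted p = 3.47e-14), Rragd by 5.79 (adjusted p = 8.05e-16) and Khdc3 by 3.17 (adjusted p = 6.33e-11). Wee2, Bmp15 and Zar1 changed by -7.78 (adjusted p = 5.15e-18), -6.49 (adjusted p = 8.28e-14) and -5.34 (adjusted p = 5.92e-17). Of the enzymes that write and remove DNA methylation, Dnmt1, the maintenance methyltransferase, fell at the 1-cell, 2-cell and 8-cell stages, from 9009 ± 976 (SD, n = 4) in oocytes to 2606 ± 190, 571.6 ± 291 and 178.2 ± 108. In blastocysts it read 311.8 ± 125. The brightest tested probe set of Dnmt1 was of the x_at type, which can share sequence between genes. Tet1, a dioxygenase that oxidizes methylcytosine, read 57.1 ± 33.8 in oocytes and 1997 ± 385 in blastocysts on one probe set and 117.9 ± 6.13 and 1385 ± 352 on another. Between oocyte and 1-cell these probe sets differed, with log2 changes of 0.30 (adjusted p = 0.649) and -1.23 (adjusted p = 0.016). Tet2 rose at the 8-cell stage on both of its probe sets, from 171 ± 47.5 to 635.6 ± 130 and from 43.7 ± 38.8 to 1004 ± 395. Tet3 fell at the 2-cell stage, from 404.4 ± 191 to 85.3 ± 61.3. Other scalings moved the median log2 change of all probe sets between oocyte and blastocyst from 0.119 to 0.04 with a common 75th percentile and 0.01 with quantile normalization.

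Lists of cells that could have been carried over gave no call by camera. Fry, which asks only whether a list's genes change on average, called cumulus and granulosa genes at the 2-cell (adjusted p = 3.99e-05) and blastocyst stages (adjusted p = 0.000205). It called sperm and spermatid genes at the 1-cell (adjusted p = 0.022), 2-cell (adjusted p = 0.0253) and 8-cell stages (adjusted p = 0.000278). Such calls do not mean that the genes moved together. At the 2-cell stage 5 of 9 cumulus and granulosa genes had log2 changes above 0, and at the 1-cell stage 11 of 21 sperm and spermatid genes. Of 9 measured cumulus and granulosa genes, 0, 1, 0 and 0 rose and 0, 1, 1 and 1 fell over the 4 comparisons, with camera adjusted p values of 0.84, 0.708, 0.979 and 0.182. The 2-cell fall, of Cyp11a1, with 1-cell replicate 2 apart at 219.8, was lost on only the 8 arrays compared (adjusted p = 0.0597) and without 1-cell replicate 2 (adjusted p = 0.0534) or 2-cell replicate 4 (adjusted p = 0.066). Amhr2, the anti-Müllerian hormone receptor, read 196.4 ± 23.3 (SD, n = 4) in oocytes and 2053 ± 284 at the 2-cell stage, and Foxl2, a granulosa transcription factor, 760 ± 96.3 in oocytes and 624.1 ± 149 in blastocysts. Of 21 sperm and spermatid genes 0, 3, 1 and 1 rose and 3, 0, 2 and 1 fell, with camera adjusted p values of 0.707, 0.831, 0.84 and 0.798. The 3 falls at the 1-cell stage were of Txndc2 (-1.15 log2 units), Tekt4 (-1.48) and Catsper2 (-1.0, with oocyte replicate 4 apart at 181.1). The call of Catsper2 was lost without oocyte replicate 4 (adjusted p = 0.0682) and on only the 8 arrays compared (adjusted p = 0.0613). That of Tekt4 was lost with a pseudocount of 5 (adjusted p = 0.0559) and without oocyte replicate 2 (adjusted p = 0.0724), 1-cell replicate 2 (adjusted p = 0.0798) or 1-cell replicate 3 (adjusted p = 0.0522). Of the 2-cell rises, that of Txndc2 was lost with any array of the 2 stages left out except 2-cell replicate 4 (adjusted p from 0.0581, without 1-cell replicate 3, to 0.14, without 1-cell replicate 2). It was also lost with a pseudocount of 5 (adjusted p = 0.0977), no filter (adjusted p = 0.0543), a common 75th percentile (adjusted p = 0.0824), the replicate block (adjusted p = 0.063) and no intensity trend (adjusted p = 0.0609). The rise of Odf2 was lost with quantile normalization (adjusted p = 0.0509) and without 1-cell replicate 1 (adjusted p = 0.0909), 1-cell replicate 3 (adjusted p = 0.0693), 2-cell replicate 1 (adjusted p = 0.0639) or 2-cell replicate 3 (adjusted p = 0.0733). The 8-cell rise, of Catsper2, with 8-cell replicate 2 apart at 536, was lost without 2-cell replicate 1, 3 or 4 (adjusted p = 0.116, 0.0674 and 0.13) or 8-cell replicate 2 or 4 (adjusted p = 0.197 and 0.0565). Pseudocount 5, no filter, quantile normalization, a common 75th percentile and only the 8 arrays compared also lost it (adjusted p = 0.0622, 0.0572, 0.0511, 0.0587 and 0.0554). The 8-cell fall of Zpbp was lost on only the 8 arrays compared (adjusted p = 0.0758) and without 2-cell replicate 2 (adjusted p = 0.0618), 8-cell replicate 2 (adjusted p = 0.0786) or 8-cell replicate 4 (adjusted p = 0.0585). The blastocyst fall of Tekt4 was lost without 8-cell replicate 2 (adjusted p = 0.0522). Txndc2, a thioredoxin of sperm, fell from 1092 ± 171 at the 2-cell stage to 24.1 ± 0.67 at the 8-cell stage. Only 2 genes of the blood and reproductive tract list and 3 of the cytosolic ribosomal protein list were measured, too few for a test. Dnah9, of the former, fell from 567.5 ± 49.8 at the 2-cell stage to 189 ± 60.6 at the 8-cell stage. Its rise at the 1-cell stage (0.57 log2 units, adjusted p = 0.132) was called with array weights (adjusted p = 0.0476) and on only the 8 arrays compared (adjusted p = 0.0201). Laptm5, the other, fell from 146.7 ± 23.6 at the 8-cell stage to 62.8 ± 37.3 in blastocysts (adjusted p = 0.0237). That call was lost on only the 8 arrays compared (adjusted p = 0.0719) and without 8-cell replicate 1 (adjusted p = 0.0644), 8-cell replicate 4 (adjusted p = 0.057), blastocyst replicate 1 (adjusted p = 0.0715) or blastocyst replicate 2 (adjusted p = 0.106).

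Other lists gave no call by camera on all arrays in any of the 4 comparisons. Fry called mRNA decay in all 4 (adjusted p = 0.0328, 3.99e-05, 0.00135 and 0.00292). The mean log2 changes of that list were -0.102, -0.185, 0.127 and 0.106, so their sign changed. Fry also called cholesterol biosynthesis in the first 3 (adjusted p = 0.000278, 4.42e-07 and 0.000334). There the mean log2 changes were 0.369, -0.458 and 0.468. Glycolysis was called by fry at the 2-cell and 8-cell stages (adjusted p = 0.000328 and 0.00135). At the 2-cell stage fry called nuclear transport and chromatin modifiers (adjusted p = 0.000278 and 0.00132). The camera adjusted p values from the first to the last comparison were 0.808, 0.347, 0.41 and 0.60 for 43 genes of mRNA deadenylation and decay. They were 0.839, 0.985, 0.537 and 0.831 for 57 of meiosis and the spindle, and 0.96, 0.84, 0.96 and 0.96 for 82 chromatin modifiers. For the rest they were 0.98, 0.839, 0.338 and 0.84 for 17 of glycolysis, 0.996, 0.707, 0.831 and 0.831 for 27 of nuclear transport and 0.0851, 0.164, 0.708 and 0.84 for 8 of cholesterol biosynthesis.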

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

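All tests of the 18S ribosomal RNA signal were chosen after it was seen. Of 347 groups of 4 arrays examined for an array far from the other 3, 29 lay above Dixon's critical value. For normally distributed values chance gives about 1 in 20 groups, or 17.4. The ratios of genes were taken on linear intensities, which are skewed, so the excess cannot be read as odd arrays. Among measures of whole arrays, 2-cell replicate 1 had a lower median intensity (81, others from 87.3 to 87.5; ratio 0.969) and 75th percentile (185.8, others from 192.8 to 193.8; 0.863). Blastocyst replicate 3 was apart on the first principal component (74.8, others from 83.5 to 84.7; 0.888), and blastocyst replicate 4 in the 3'/5' log2 ratio of beta-actin (0.68, others from 1.22 to 1.25; 0.949).

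Among named genes, a single array stood apart for Cep164 (ratio 0.914), Ipcef1 (0.953), Tnks (0.979), Ndufaf6 (0.86) and Catsper2 (0.889) in oocytes. At the 1-cell stage this held for Ndufaf6 (0.888), Cyp11a1 (0.873) and Cdk13 (0.854). At the 2-cell stage it held for Zfp873 (0.975), Fbxw22 (0.864), Vnn1 (0.88) and Rnaseh2b (0.887), all highest on replicate 1, for Wdr3 (0.846) on replicate 3 and for Mtrf1l (0.867) on replicate 2. At the 8-cell stage the genes were Wee2 (0.908), Nlrp4f (0.973), Bmp15 (0.845), Ddx46 (0.861), Klf17 (0.845), Amhr2 (0.83), Catsper2 (0.893), Tmem125 (0.889), Obox6 (0.894) and Cdk13 (0.846), and in blastocysts Klf17 (0.955). No explanation of these was tested.

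A signal outside the tested probe sets is that of 18S ribosomal RNA, whose middle control probe set had a mean intensity of 37010 on the 1-cell arrays. A common scale factor is argued against, since the 3' control probe sets of Gapdh and beta-actin rose by 0.31 and 0.36 log2 units from oocyte to 1-cell against at least 4.13 for the 18S probe sets; the bacterial control probe sets rose by a median of 0.703, but how these RNAs were added is not given in the sources used here. A single array is argued against too: the lowest 1-cell array was at least 2.70 times the highest of the other 16 in all 3 probe sets. Whether ribosomal RNA diluted the other transcripts cannot be told apart from no dilution, because the authors' scaling of each array to 1 mean holds the median change near 0 in either case (0.017). The signal may reflect the 1-cell stage or a different preparation of the 1-cell RNA; stage and preparation coincide in this design.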

How the results depend on the processing

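Array weights and the counts of probe sets lowest or highest at the 1-cell stage were chosen after seeing the data. The alternatives were applied to 164 named-gene results and 72 list results, and none that was called as reported changed direction. Reversals were not counted for results without a call. Among those, the median of cholesterol biosynthesis at the 2-cell stage ranged from -0.88 to 0.12, for example. Dnmt1, the Tet genes, the genes named for the 1-cell dip below and single-gene changes between oocyte and blastocyst were not put through the alternatives. List medians moved in size. That of oxidative phosphorylation in blastocysts ranged from 0.18 to 0.51, and that of maternal genes there from -0.74 to -0.36. For mitochondrial ribosomal proteins at the 8-cell stage it ranged from 0.33 to 0.73. Between oocyte and 1-cell the 406 higher probe sets became 179 at a minimum of 2-fold and 612 with array weights, and ranged from 257 (without 1-cell replicate 2) to 438 with an array left out; the 1003 lower in blastocysts than at the 8-cell stage became 653 at 2-fold. The other counts of probe sets stayed within 1.5 times under every alternative, except those highest at the 1-cell stage. Those numbered 100, but 187 with a pseudocount of 80, 23 with quantile normalization, 32 without an intensity trend and 197 with array weights, and 20 (without 1-cell replicate 2) to 103 with an array left out; leaving out oocyte replicate 1, 2 or 4 gave 51, 52 and 37, and 1-cell replicate 1 or 3 gave 57 and 32. The count highest at the 1-cell stage therefore carries little weight. Of the 2 lists called between oocyte and 1-cell, 1 was called with a pseudocount of 80, no filter, the 75th percentile filter, no intensity trend, no x_at or s_at probe sets, or array weights (the proteasome was lost in each, except oxidative phosphorylation without x_at and s_at), 0 with an estimated correlation and 7 with fry; with an array left out, 1 (without oocyte replicate 2, oocyte replicate 4 or 1-cell replicate 2) to 4 (without 1-cell replicate 4). Fry called 15 lists in place of 3 at the 2-cell stage and 14 in place of 5 at the 8-cell stage. In blastocysts it called 8 in place of 4, where an estimated correlation left 1. Fry asks another question, whether the list's genes change on average, and the cause of the other changes was not tested. Replicate numbers do not pair the arrays: across stages, arrays with the same number correlated at -0.06 to 0.06 after removal of stage means, and 4 of 20 arrays were closest to their own number. With the replicate number as a block, counts were close to those above, for example 402 and 645 at the 1-cell stage and 220 peaks at the 2-cell stage. The lowest intensities are limited by background.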

Other observations

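The tests of probe sets lowest or highest at the 1-cell stage, and among them the tests with the 1-cell arrays divided and with other splits for the highest, and the sorting of the splits for lists by arrays exchanged were chosen after the result was seen. Of 649 probe sets called lower at the 1-cell stage than in oocytes, 261 (40.2%) were then called higher at the 2-cell stage. Of all tested probe sets 12.2% rose there, and independent lists of these sizes would share 79.2. Both comparisons use the same 1-cell arrays, which by itself raises the overlap, and neither figure was matched on intensity. A test for being lowest at the 1-cell stage called 188, among them Mrpl43, a mitochondrial ribosomal protein, at 369.4 ± 22.9 (SD, n = 4), 27.5 ± 9.27 and 611.4 ± 128 through the oocyte, 1-cell and 2-cell stages. Pfdn6, a prefoldin subunit, read 1836 ± 200, 235.7 ± 46.3 and 2135 ± 433, Rpl22, a ribosomal protein, 5431 ± 979, 960.9 ± 172 and 5354 ± 813, and Cnot10, of the deadenylase complex, 1405 ± 218, 225.8 ± 86.0 and 814.8 ± 95.2; these genes were chosen after their values were seen. The 150 named genes, of 7490 tested, held 7 of 53 ribosome biogenesis genes, 5 of 82 chromatin modifiers and 4 of 24 mitochondrial ribosomal proteins. They held 2 each of oxidative phosphorylation, mRNA decay and nuclear transport, 0 of 48 oocyte and maternal-effect genes and at most 1 of any other list. List sizes rest on 1 probe set per gene, whereas the called probe set could be another, as for Cnot10. Of the 2 Tet1 probe sets given above, only 1 fell at the 1-cell stage. Enrichment was not tested.

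For this dip, array scaling is argued against by a count of 159 under the lower of 2 other scalings, and a single 1-cell array by a count of at least 142 with any of them left out. With the fall read from 2 of the 1-cell arrays and the rise from the other 2, the overlap was at least 3.04 times that of independent lists. So the overlap did not need the same arrays in both comparisons, although the independent lists were not matched on intensity. Noise or preparation common to all 1-cell arrays enters both sets of arrays, so this division cannot speak on it. The dip may reflect transcripts lost or shortened at their tails by the 1-cell stage and renewed at the 2-cell stage, which was not tested. It may also reflect the preparation of the 1-cell RNA, on which 18S ribosomal RNA was also high. Stage and preparation coincide, so this stays open.

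The hypothesis that 2-cell peaks are rich in probe sets without a gene symbol failed. They made up 14.6% of the peaks against 30.1% of tested probe sets, and the share ranked at percentile 0 among 10000 lists matched on intensity. Against peaks at the 1-cell or 8-cell stage (11.9%) Fisher's exact p was 0.425.

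The same arrays were also divided in other ways into groups of the same sizes. For the counts of probe sets in the 5 comparisons, fitted on 8 arrays, only the real split of 35 (1 of them) gave as many. It gave 1229, 3180, 4026 and 1901 in the consecutive comparisons and 5576 between oocyte and blastocyst, against at most 0 in the others. The other splits mix stages within each group, which widens the spread and leaves few calls. So the arrays differ by stage label, but such splits cannot tell stage from preparation or embryo pool. Over 100 splits the real one gave 8078 probe sets changed among the 5 stages (highest other 1656) and 221 peaks at the 2-cell stage (highest other 0). It gave 66 lowest at the 2-cell stage (highest other 7) and 151 lowest at the 1-cell stage (highest other 4), with the same limits. Counts of peaks, lowest and highest were fitted on only the arrays of that stage and its neighbours. They therefore differ from those of the fit on all arrays. For those highest at the 1-cell stage, 2 of 100 splits gave as many. The real count was 163 and the highest other 1050. A drawn split can give the 1-cell label to arrays of another stage, and which arrays that split grouped was not examined. For the lists, this count does not exclude chance in any comparison, nor does it speak for chance: the real count and the highest other were 1 and 1 (2 of 35 splits as large) at the 1-cell stage, 3 and 3 (5 of 35) at the 2-cell stage, 5 and 7 (8 of 35) at the 8-cell stage and 4 and 4 (2 of 35) in blastocysts. All of the other splits with as many exchanged 1 array of each stage, which leaves part of the stage difference in; of the 18 that exchanged 2, 0 gave as many, and the highest were 0, 0, 1 and 1.

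Placed between the mean 1-cell (0) and 8-cell (1) profile, the 2-cell arrays of replicates 1 to 4 lay at 0.287, 0.384, 0.461 and 0.419 over 2514 falling probe sets and at 0.416, 0.502, 0.588 and 0.55 over 3571 rising ones. The transferrin receptor, read by a control probe set at its 3' end, was at 67.7 ± 23.3 (SD, n = 4) in oocytes, 75.5 ± 16.9 at the 1-cell, 1990 ± 464 at the 2-cell, 1408 ± 275 at the 8-cell and 131.2 ± 52.9 at the blastocyst stage. Its 5' probe set rose less from 1-cell to 2-cell, from 75.9 ± 21.4 to 142.3 ± 34.6. Of 2 control probe sets of the B2 repeat, 1 read 21180 ± 3210 in oocytes and 58030 ± 12100 at the 8-cell stage and the other 1137 ± 378 and 6196 ± 2060, while a bacteriophage P1 cre control, no transcript of the embryo, went from 25610 ± 4170 to 68870 ± 15200 and the B1 repeat control from 8483 ± 1930 to 6452 ± 3130.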
